A study of Mus musculus with 27 samples.

How the data were processed

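The values were deposited as 1 table of probe-set intensity on a linear scale, for 27 Affymetrix mouse expression arrays and 45037 probe sets. GCOS was the only tool named, per the submitters' processing notes, and its version, the summary algorithm and the background correction were not given in the sources used here. The deposited intensity columns had medians from 0.996 to 1, so each array had been divided by its own median before deposit. Total RNA was isolated with TRIzol and labelled as biotinylated cRNA, per the labels' protocols. Cells were cultured with TNFα at 5 ng/ml and an antibody to the lymphotoxin beta receptor at 1 µg/ml, and stimulated with Pam2CSK4 at 100 ng/ml, LPS at 20 µg/ml or all-trans-retinoic acid at 40 nM, per the labels' protocols. The dose of Pam3CSK4 and the culture time of the unstimulated arrays were not given in the sources used here. For Pam2CSK4 replicate 1 the description gave 72 h and the title and source gave 96 h, and the 96 h of the title was used.

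The 2% trimmed mean differed between the sets of arrays, from 5.19 to 6.68 in the first and from 8.39 to 16.4 in the second. The design had taken the table to be scaled to a trimmed mean of 500, which the values did not show, so each array was scaled to a 2% trimmed mean of 500. A value of 32 was then added and log2 taken, so that fold changes are on the log2(intensity + 32) scale and understate the change of dim genes. After this scaling, array medians ran from 74.6 to 96.0 in the first set and from 30.6 to 59.6 in the second. Tests that used both sets compared differences taken within each set or had a term for the set, and only the starting levels of 2 genes are given for both sets, without a test.

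Gene names came from the platform annotation, which named 1 gene for 34945 probe sets, several for 932 and none for 9160. Of the probe sets with 1 gene, 34741 matched a table of RefSeq genes of assembly GRCm38.p6 by Entrez number, and 0 symbols needed an update. These probe sets named 18193 genes. A probe set with several genes was not used under any of their names, and Tnfsf13, one of the genes chosen in advance, had no usable probe set. Probe sets above the median of their array in at least 2 of the 18 arrays of the first set were kept, and the probe set with the highest mean stood for its gene, which left 13130 genes.

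A linear model over the 18 arrays of the first set, with 9 groups sharing 1 estimate of the spread, was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend). P-values were adjusted by Benjamini and Hochberg over the 13130 genes of each comparison, with a threshold of 0.05. The 2 LPS groups had 1 array each, so their tests borrowed the spread of the other groups. Pam3CSK4 was compared with Pam2CSK4 in a model over both sets, as the change from the unstimulated arrays of the same set. The arrays of the second set were otherwise described by differences without a test.

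Before the data were examined, 27 gene lists were fixed. These covered FDC-associated genes, B-cell attractants and survival factors, TGF-beta production and activation, Toll-like and NOD receptors and adaptors, NF-kB and inflammatory response genes, retinoid receptors and metabolism, interferon-stimulated genes, MHC class II presentation and costimulation, complement and Fc receptor genes, the cell cycle, and extracellular matrix and contractile fibroblast genes. The other lists held markers of B cells, germinal-centre B cells, plasma cells, T cells, macrophages, dendritic cells, neutrophils, gut epithelium, blood and lymphatic endothelium, fibroblastic reticular cells, pericytes and smooth muscle, mast cells, adipocytes, erythroid cells and Schwann cells. The adipocyte, erythroid and Schwann-cell lists had fewer than 3 measured members and were not tested. Each of the other 24 lists was tested against the remaining genes with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation; fry served as an alternative. Beside each list stands the number of members past the threshold over all genes, and the number when the p-values were adjusted over the list alone. For single arrays, the median of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins.

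The genes to be named were set by a rule written in advance. It took 16 genes chosen in advance (Cxcl13, Tnfsf13b, Tnfsf13, Tgfb1, Ltbp3, Mmp2, Mmp9, Tlr2, Tlr4, Cd14, Rarb, Icam1, Vcam1, Madcam1, Mfge8 and Cr2), then the 8 genes with the largest difference in each direction that passed the threshold with no overlap between the groups, then up to 4 members with the smallest p of each list that passed its test or had at least 3 members past the threshold. Provisional symbols were passed over. For the second set the rule took the same chosen genes and the 5 largest differences per direction among genes above the 75th percentile of 1 of the arrays. The comparisons of RA plus Pam2CSK4 with either stimulus alone and of LPS at 72 h with 5 h were added after the data were seen.

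The replicate numbers came from the titles, and whether they pair arrays was checked by the correlation of same-numbered arrays' deviations from their group means. For naive lymph node and Peyer's patch arrays these correlations were 0.562, 0.505 and 0.431, all above 0.1, so the numbers were taken to pair those arrays. For that comparison, values with the number as a block are given beside the result where they change a call or move a count by over 1.5 times. Groups of 2 arrays have deviations that mirror each other, so pairing was not judged there. For these other groups the counts with the block are given with the sensitivity results.

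Alternatives were quantile normalization, added values of 8 and 128, no filter and a 75th percentile filter, the mean of a gene's probe sets, no intensity trend, array quality weights, each replicate left out, the spread of the compared groups only, the second set's naive and unstimulated arrays added, and the replicate block. The deposited median scaling, a term for the number of decimals in an array's values and the removal of arrays written with 4 decimals were added after the data were seen. Methods were tested on simulated data built from these arrays with genes changed by known amounts. Of genes changed by 1 log2 unit, 42% were recovered for Peyer's patches against naive lymph nodes, 24% for Pam2CSK4, 30% for RA, 9% for LPS at 5 h and 1% for the RA by Pam2CSK4 interaction. At 2 log2 units the shares were 99%, 86%, 94%, 73% and 40% in the same order. Further tools were matrixStats 1.5.0, statmod 1.5.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.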

Results

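Gene expression was measured in follicular dendritic cell (FDC) preparations from wild-type Balb/c mice. FDCs are stromal cells of B-cell follicles that hold antigen and attract B cells. The first set of 18 arrays held freshly prepared cells from peripheral lymph nodes (pLN) of naive mice (3 arrays), pLN after immunization with the hapten-carrier antigen TNP-KLH in incomplete Freund's adjuvant (2) and Peyer's patches (3). It also held cultured FDCs without a stimulus (2), with the Toll-like receptor 4 ligand LPS for 5 h (1) or 72 h (1), and with the Toll-like receptor 2 ligand Pam2CSK4 (2), all-trans-retinoic acid (RA, 2) or both (2) for 96 h. A second set of 9 arrays had 1 array in each of 9 groups and no replicates. Replicate arrays of the first set correlated with r from 0.947 to 0.984. The labels did not say whether replicates came from separate animals or cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. Macrophage transcripts were abundant in the preparations. The median macrophage marker lay at percentile 94.9 of all genes in naive pLN, 98.4 in Peyer's patches and 83.7 in unstimulated culture. For FDC-associated genes the percentiles were 83.2, 88 and 83.7. Which cells in a preparation a change came from was not tested.

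Peyer's patches lie in the gut wall and are a site of IgA induction, and the first comparison asked how their FDC preparations differ from those of naive pLN. Interferon-stimulated and mast-cell genes were lower in Peyer's patches as lists, while single genes for B-cell support, retinoid synthesis and TGF-beta handling were higher in lists that did not pass with an estimated correlation. Tnfsf13b, which encodes the B-cell survival factor BAFF, was 2.46 ± 0.20 log2 units higher (SE, 3 arrays against 3; adjusted p = 1.71e-06). Ltbp3, a carrier of latent TGF-beta, was 2.23 ± 0.29 higher, and the matrix metalloproteinases Mmp2 and Mmp9 were 2.74 ± 0.34 and 2.79 ± 0.29 higher. In all, 1056 of 13130 genes differed, 544 higher and 512 lower, and 747 of them at least 2-fold. With the replicate number as a block the count was 1653. The groups did not overlap for 2565 genes, where chance alone gives 10% of all genes.

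Members of the B-cell attractant and survival list that rose in Peyer's patches were Tnfsf13b, Kitl (1.75 ± 0.27), Cxcl12 (1.01 ± 0.25) and Cxcl13 (1.21 ± 0.35), and Il15 fell by 1.65 ± 0.22. That is 4 higher and 1 lower of 9 measured members, and 6 and 2 when adjusted over the list alone (camera adjusted p = 0.0386, and adjusted p = 0.181 with an estimated correlation). The list median was 0.84 over all arrays, 1.69 between the replicate 1 arrays, whose values were written with 4 decimals, and 0.59 between the others, written with 3. For Cxcl13, the follicular B-cell attractant, the adjusted p was 0.0456 and the groups overlapped. Its adjusted p ran from 9.12e-05 to 0.21 over the alternatives, and was 0.0635, 0.125 and 0.102 without naive replicate 1, 2 or 3 and 0.174 and 0.175 without Peyer's patch replicate 1 or 3. The value for Cxcl12 passed at 0.0201, with a range of 0.00297 to 0.302, and did not pass without naive replicate 1 (0.0666) or 2 (0.0508) or Peyer's patch replicate 1 (0.0883). With the mean of its probe sets Cxcl12 was at 0.40 (0.302).

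Of 14 FDC-associated genes, 5 were higher and 1 lower, and 6 and 2 when adjusted over the list alone. Mfge8, a bridge for dying cells on FDCs, rose by 2.51 ± 0.54, the adhesion ligand Madcam1 by 2.44 ± 0.45 and the clusterin gene Clu by 1.94 ± 0.40. Cr2, the complement receptor that holds antigen, rose by 1.97 ± 0.53 (adjusted p = 0.0314, range 0.00151 to 0.138), and did not pass without naive replicate 2 (0.0668) or 3 (0.121) or Peyer's patch replicate 1 (0.117, at 1.21) or 3 (0.0667). Icam1 (-0.11) and Vcam1 (0.32) did not pass. The list as a whole passed with camera at 0.0426, and had an adjusted p = 0.396 with an estimated correlation. Its median was 0.45, with 0.55 between the 4-decimal arrays and 0.35 between the 3-decimal arrays.

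Retinoid genes formed the next group, with 7 higher and 1 lower of 18 measured (9 and 3 adjusted over the list alone; camera adjusted p = 0.00361, and adjusted p = 0.0872 with an estimated correlation). The RA-producing dehydrogenases Aldh1a3 and Aldh1a1 rose by 3.14 ± 0.34 and 2.18 ± 0.32, the retinol-storing enzyme Lrat by 3.01 ± 0.51 and Rdh10 by 0.80 ± 0.18. The RA receptor gene Rarb was 1.02 higher without passing (adjusted p = 0.126), and passed with the replicate block (0.0465). In the TGF-beta list 5 of 18 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.0181, and adjusted p = 0.204 with an estimated correlation). Ltbp3, Mmp2 and Mmp9 were among the 5, the co-receptor Tgfbr3 fell by 1.97 ± 0.28, and Tgfb1 itself was at -0.05 (adjusted p = 0.968). The medians between the 4-decimal and between the 3-decimal arrays were 0.8 and 0.65 for the retinoid list and 0.55 and 0.5 for the TGF-beta list, against 0.52 for each list over all arrays.

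Interferon-stimulated genes fell together, with 17 of 18 lower, also when adjusted over the list alone (median -1.77; camera adjusted p = 1.21e-27). Ifit1 fell by 3.20 ± 0.32, Ifit3 by 2.62 ± 0.20, Mx1 by 2.47 ± 0.26 and Usp18 by 2.25 ± 0.20. The median was -2.12 between the 4-decimal arrays and -1.59 between the 3-decimal arrays. In the NF-kB and inflammatory list 5 of 23 were lower and 1 higher (7 and 2 adjusted over the list alone), with Saa3 at -2.95 ± 0.31 and Cxcl1 at 1.84 ± 0.27. The test of that list gave a lower direction at 0.0393, with adjusted p = 0.204 with an estimated correlation and 0.0601 with the replicate block. Of 21 Toll-like and NOD receptor genes 4 were lower and 1 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.0554). Tlr3 fell by 1.17 ± 0.23, Tlr4 by 0.70 ± 0.16 and Tlr2 by 1.03 ± 0.26. For Tlr2 the adjusted p was 0.0201 (range 0.00218 to 0.134), and 0.104 without naive replicate 3 and 0.0907 without Peyer's patch replicate 1. For Tlr4 it was 0.0105 (range 0.00336 to 0.358), and 0.358 with the mean of its probe sets, at -0.47. The co-receptor gene Cd14 was at 0.31 and did not pass.

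Markers of other cells moved with the tissue. All 7 mast-cell markers were lower (median -3.21, camera adjusted p = 8.03e-16, 7 adjusted over the list alone), among them the protease genes Cpa3 (-5.68 ± 0.40) and Cma1 (-4.78 ± 0.32). The protease gene Tpsab1, which is not in the list, was at -4.45 ± 0.41. Neutrophil markers had 5 of 7 lower and 7 adjusted over the list alone (camera adjusted p = 4.61e-07, and adjusted p = 0.0872 with an estimated correlation), with S100a8 at -3.30 ± 0.61. Gut epithelial markers had 7 of 11 higher and 8 adjusted over the list alone (camera adjusted p = 4.52e-07, and adjusted p = 0.11 with an estimated correlation). Of that list, Fabp2, which binds fatty acids in enterocytes, rose by 5.71 ± 0.42 and the keratin Krt8 by 2.97 ± 0.53. The related Fabp1, which is not in the list, rose by 4.59 ± 0.60. Extracellular matrix genes had 7 of 19 higher and 10 adjusted over the list alone (camera adjusted p = 1.02e-05, and adjusted p = 0.181 with an estimated correlation), among them Dcn (1.86 ± 0.34) and Lum (1.84 ± 0.31). Cell cycle genes had 4 of 19 higher and 8 adjusted over the list alone (camera adjusted p = 0.00037, and adjusted p = 0.204 with an estimated correlation), with Cdk1 at 0.88 ± 0.18. Igha, the IgA heavy chain, was the gene with the largest rise named by the rule, at 5.87 ± 0.33, followed by Fabp2 and Adamdec1 (5.36 ± 0.27). B-cell markers had 2 of 8 higher and 3 adjusted over the list alone, with Cd79b at 1.72 ± 0.29. That list passed at 0.0386, had an adjusted p = 0.222 with an estimated correlation and 0.055 with the replicate block, and its median was -0.15 between the 4-decimal arrays and 0.78 between the 3-decimal arrays. Macrophage markers had 1 of 11 higher, also adjusted over the list alone (camera adjusted p = 0.0393, and adjusted p = 0.252 with an estimated correlation). Between the 4-decimal and between the 3-decimal arrays the medians were 2.22 and 1.42 for the epithelial list, -2.47 and -3.58 for the mast-cell list, -2.92 and -1.3 for the neutrophil list and 1.38 and 0.59 for the matrix list. With the replicate block further genes passed, among them the germinal-centre regulator Bcl6 (-0.91; adjusted p = 0.0606 without and 0.00223 with the block), Fas (-1.32; 0.14 and 0.0315), Ms4a1 (1.11; 0.0928 and 0.0401), C1qc (1.03; 0.0919 and 0.019) and Mrc1 (0.79; 0.16 and 0.0382). Single arrays moved some of these, with Fas at -0.54 without Peyer's patch replicate 2 (adjusted p = 0.457, range 0.0315 to 0.457), C1qc at 0.59 without naive replicate 3 (0.37, range 0.012 to 0.37) and Mrc1 at 0.50 without naive replicate 1 (0.39, range 0.0382 to 0.39).

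Whether immunization with TNP-KLH moved pLN preparations from the naive state was asked next (2 arrays against 3). The myelin gene Pmp22 fell by 1.90 ± 0.26 and Foxred2 by 1.71 ± 0.22, each at an adjusted p = 0.0119 with limma, and no gene rose. The count at an unadjusted p under 0.05 was 1223 genes. The count of 2 became 0 without naive replicate 1 or 2 or TNP-KLH replicate 2, and 31 without naive replicate 3. The proliferation marker Mki67 was at 1.45 ± 0.32 (adjusted p = 0.168) and Ifit3 at -1.08 (0.163), neither past the threshold. The interferon-stimulated list had 0 members past the threshold and 3 lower when adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.629 with an estimated correlation). Cell cycle genes had 2 higher when adjusted over the list alone (camera adjusted p = 0.0265, and adjusted p = 0.629 with an estimated correlation). Mast-cell markers had 2 lower by the same count (camera adjusted p = 0.0013, and adjusted p = 0.629 with an estimated correlation).

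Peyer's patches were also set against immunized pLN (3 arrays against 2), to ask which tissue differences stand when the lymph node had met antigen. Tnfsf13b was 2.53 ± 0.23 higher, Ltbp3 2.32 ± 0.33 and Mmp2 4.22 ± 0.39. Madcam1 was 2.68 ± 0.51 higher (adjusted p = 0.00378) and Mfge8 2.77 ± 0.60 (0.00948), and the adjusted p without TNP-KLH replicate 2 was 0.0729 for Madcam1 and 0.102 for Mfge8, which also stood at 0.0716 without replicate 1. Over the alternatives these ran from 0.000143 to 0.0729 and from 0.000505 to 0.102. Cxcl13 (0.83; adjusted p = 0.226) and Cr2 (1.83; 0.0747) did not pass. In all 999 genes differed, 598 higher and 401 lower, and the count was 363 without TNP-KLH replicate 1 and 291 without replicate 2. The arrays of Peyer's patches are the same as in the comparison with naive pLN.

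Retinoid genes had 6 higher of 18 in that comparison and TGF-beta genes 4 of 18, with 7 higher and 1 lower and 6 higher and 1 lower when adjusted over the list alone. Camera gave 0.000535 and 0.00036, with adjusted p = 0.0523 and adjusted p = 0.107 with an estimated correlation. Aldh1a3 was at 3.27 and Lrat at 3.18. Interferon-stimulated genes had 13 of 18 lower and 14 adjusted over the list alone (camera adjusted p = 7.26e-16), and the inflammatory acute-phase gene Saa3 was at -4.84 ± 0.35. Toll-like and NOD receptor genes had 6 of 21 lower and 1 higher (7 and 1 adjusted over the list alone) (camera adjusted p = 0.0459, and adjusted p = 0.32 with an estimated correlation). Gut epithelial markers had 7 of 11 higher and 9 adjusted over the list alone (camera adjusted p = 7.85e-07, and adjusted p = 0.107 with an estimated correlation). Macrophage markers had 3 of 11 higher and 5 adjusted over the list alone (camera adjusted p = 0.0155, and adjusted p = 0.253 with an estimated correlation). Mast-cell markers had 5 of 7 lower and 6 adjusted over the list alone (camera adjusted p = 2.48e-09, and adjusted p = 0.0523 with an estimated correlation).

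**Figure D1:**
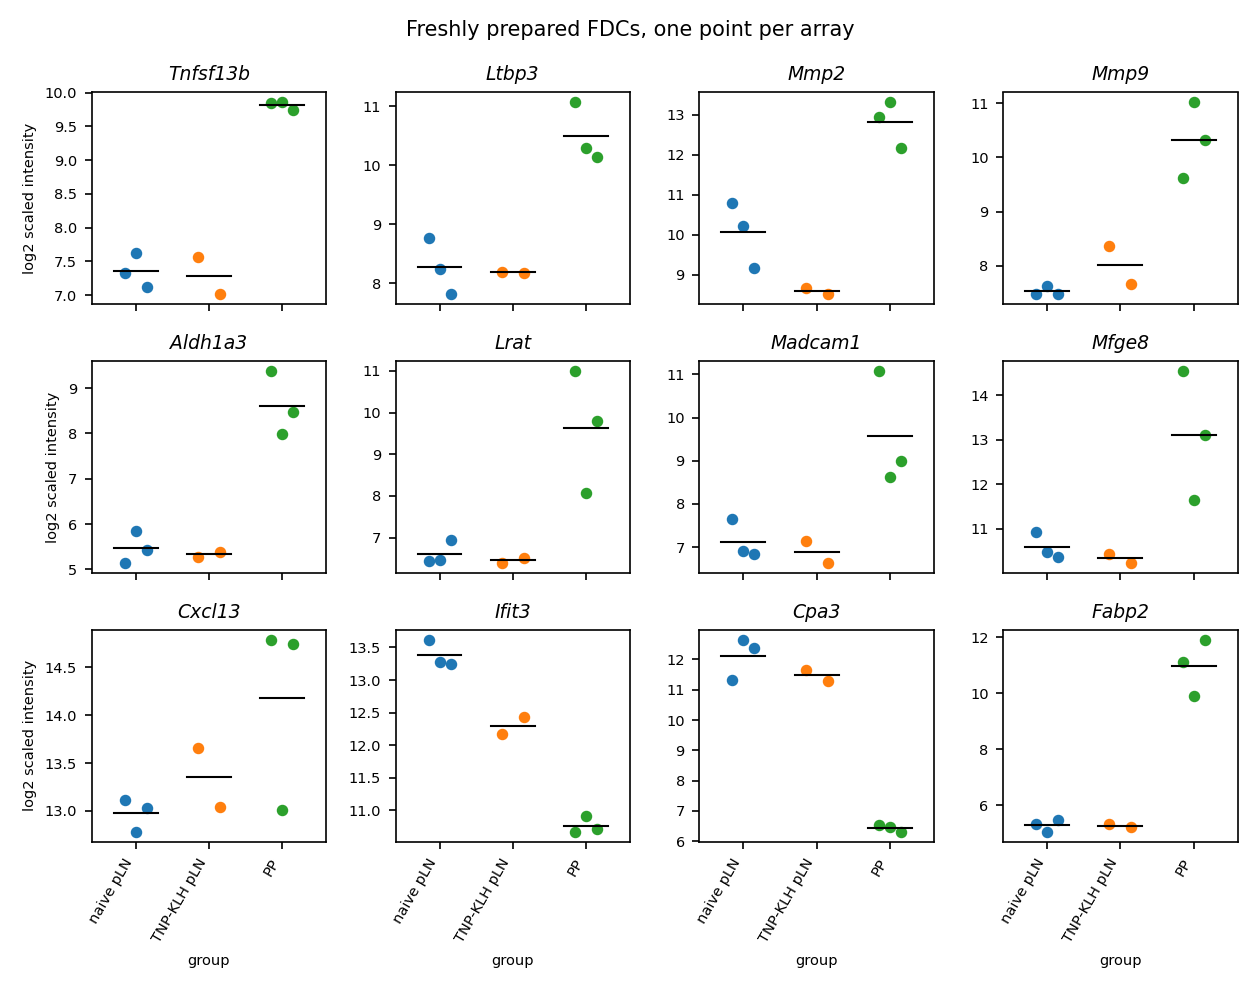
Expression of 12 genes in fresh FDC preparations, as log2 scaled intensity on the vertical axis, for naive pLN, TNP-KLH immunized pLN and Peyer's patches. Each point is an array and each line a group mean. Tnfsf13b, Ltbp3, Mmp2 and Fabp2 are higher in Peyer's patches (2.46, 2.23, 2.74 and 5.71 log2 units over naive pLN) and Ifit3 and Cpa3 are lower (-2.62 and -5.68).

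Culture itself was examined by setting unstimulated cultured FDCs against naive pLN preparations (2 arrays against 3). Expression moved widely, with 3498 genes past the threshold, 2178 higher and 1320 lower, and a median shift of 0.121 over all genes. Without unstimulated replicate 1 the count was 2185. Genes of the B-cell follicle stroma went both ways. Cxcl13 fell by 5.97 ± 0.39 and Vcam1 by 2.77 ± 0.32, while the podoplanin gene Pdpn rose by 3.43 ± 0.27 and Mfge8 by 1.73 ± 0.60 (adjusted p = 0.0438, range 0.00394 to 0.506). Mfge8 did not pass without naive replicate 2 (0.0827) or 3 (0.105) or unstimulated replicate 1 (0.506), where its difference was 0.79, against 2.67 without unstimulated replicate 2. Of 14 FDC-associated genes 3 were higher and 5 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.0738). B-cell attractants had 1 higher and 4 lower of 9, also when adjusted over the list alone, with Cxcl12 at -2.27 ± 0.28 (camera adjusted p = 0.00642, and adjusted p = 0.0581 with an estimated correlation).

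Cell cycle genes rose in culture, 15 of 19 with none lower, also adjusted over the list alone (median 1.70; camera adjusted p = 8.95e-10), with Rrm2 at 4.17 ± 0.27, Bub1 at 2.78 ± 0.30 and Cdk1 at 2.42 ± 0.20. Matrix genes had 9 of 19 higher and 12 adjusted over the list alone (camera adjusted p = 0.000166, and adjusted p = 0.242 with an estimated correlation), led by Tnc (4.24 ± 0.28). Mmp9 and Ltbp3 rose by 4.13 ± 0.33 and 2.28 ± 0.33. Interferon-stimulated genes had 17 of 18 lower and 18 adjusted over the list alone (median -2.40; camera adjusted p = 6.47e-23). Antigen presentation genes had 8 of 9 lower and 9 adjusted over the list alone (camera adjusted p = 1.16e-09), with the class II gene H2-Ab1 at -2.89 ± 0.30. Complement and Fc receptor genes had 9 of 15 lower and 1 higher (camera adjusted p = 4.93e-06), with C1qb at -3.24 ± 0.22. Of 23 NF-kB and inflammatory genes 12 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 2.14e-07), with Il1b at -3.56 ± 0.34. Among markers of other cells, 7 of 11 macrophage markers were lower, also adjusted over the list alone (median -1.21; camera adjusted p = 9.93e-06, and adjusted p = 0.0501 with an estimated correlation), and Cd163 fell by 3.22 ± 0.39. Mast-cell markers had 6 of 7 lower, also adjusted over the list alone (camera adjusted p = 2.83e-08), with Cpa3 at -5.76.

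The second set had 1 unstimulated and 1 naive array, and their difference has no replicate check. Ltbp3 was at -1.12 there, opposite to its rise in the first set, while Mmp9 (5.02), Mfge8 (2.71), Cxcl13 (-4.90) and Vcam1 (-2.44) had the direction of the first set. Interferon-stimulated (-2.24), antigen presentation (-2.16), NF-kB and inflammatory (-1.63) and mast-cell (-3.74) medians lay below all matched random lists, and the matrix median (1.76) stood at the 100th percentile. The cell cycle median (0.95, percentile 97) and the macrophage median (-0.59, percentile 23.1) lay inside the range of random lists.

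The effect of Toll-like receptor 2 stimulation was read from Pam2CSK4 against no stimulus (2 arrays against 2). The same 2 unstimulated arrays, of unstated culture time, served every stimulus of the first set. A deviation of these arrays or a difference in culture time could thus appear with each stimulus, and cannot be told apart from its effect. Cxcl13 rose by 6.34 ± 0.43, next to the arginase gene Arg1 (7.18 ± 0.79), the iron-binding lipocalin Lcn2 (4.75 ± 0.70) and the cytokine-signal inhibitor Socs3 (4.27 ± 0.29). In the NF-kB and inflammatory list 14 of 23 were higher and 15 adjusted over the list alone (median 1.85; camera adjusted p = 1.6e-21), among them Il1b (4.26 ± 0.37), the neutrophil attractant Cxcl1 (3.98 ± 0.33) and Il6 (3.95 ± 0.42). Complement genes had 5 of 15 higher (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.05e-06). Matrix genes had 6 of 19 higher and 12 adjusted over the list alone (camera adjusted p = 1.55e-12, and adjusted p = 0.0503 with an estimated correlation), with Col3a1 at 2.46 ± 0.30. Interferon-stimulated genes had 3 of 18 higher and 6 adjusted over the list alone (camera adjusted p = 3.39e-07, and adjusted p = 0.0503 with an estimated correlation). FDC-associated genes had 2 of 14 higher and 4 adjusted over the list alone (camera adjusted p = 0.00166, and adjusted p = 0.294 with an estimated correlation). Macrophage markers had 1 of 11 higher and 3 adjusted over the list alone (median 0.96; camera adjusted p = 0.000229, and adjusted p = 0.114 with an estimated correlation). Cell cycle genes had 1 of 19 lower, and 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.6e-06, and adjusted p = 0.114 with an estimated correlation). Mmp9 rose by 2.11 ± 0.36, whereas Tnfsf13b (0.66; adjusted p = 0.21), Mmp2 (1.24; 0.159) and Ltbp3 (0.26) did not pass. In all 245 genes changed, 193 higher and 52 lower. The count was 101 without unstimulated replicate 2, 67 without Pam2CSK4 replicate 1 and 147 without replicate 2, and 575 without the 4 arrays written with 4 decimals, none of which belongs to these groups.

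Retinoic acid alone was compared with no stimulus in the same way (2 arrays against 2). The RA target genes Cyp26b1, which degrades RA, and Rarb rose by 3.15 ± 0.41 and 2.56 ± 0.47, and 2 of 18 retinoid genes passed, with 5 adjusted over the list alone (camera adjusted p = 0.000168). Cxcl13 rose by 2.67 ± 0.43, Mmp9 by 2.42 ± 0.36, Ltbp3 by 1.91 ± 0.36 and the growth factor gene Bmp2 by 4.08 ± 0.31. Arg1 was at 7.44 ± 0.79, and the carbonic anhydrase gene Car2 fell by 2.80 ± 0.44. In all 180 genes changed, 135 higher and 45 lower, with 48 without unstimulated replicate 2, 276 without replicate 1, 46 without RA replicate 1, 40 without RA replicate 2 and 488 without the 4-decimal arrays. Single arrays also ended calls. Rarb had an adjusted p of 0.011 (range 0.00229 to 0.136), and 0.11, 0.0689 and 0.136 without unstimulated replicate 2, RA replicate 1 and RA replicate 2. For Ltbp3 (0.014, range 0.000806 to 0.245) the same arrays gave 0.245, 0.142 and 0.104. Cxcl13 (0.00464, range 0.00033 to 0.224) was at 0.0826 without unstimulated replicate 2 and 0.069 without RA replicate 2, and with the mean of its probe sets it was 1.64 higher (0.224), and Mmp9 and Car2 were at 0.0593 and 0.069 without RA replicate 2, with ranges of 0.000262 to 0.0593 and 0.000362 to 0.069.

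Complement and Fc receptor genes had 4 of 15 higher with RA and 7 adjusted over the list alone (camera adjusted p = 2.17e-08), with C1qb at 2.12 ± 0.24. NF-kB and inflammatory genes had 6 of 23 higher (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.08e-08), with Saa3 at 2.96 ± 0.38 and Il1b at 2.79 ± 0.37. Interferon-stimulated genes had 4 of 18 higher and 8 adjusted over the list alone (camera adjusted p = 3.25e-09), with Mx2 at 2.73 ± 0.34 and Ifit2 at 2.19 ± 0.31. Macrophage markers had 4 of 11 higher and 6 adjusted over the list alone (median 1.09; camera adjusted p = 1.99e-07). Cell cycle genes had 1 of 19 lower and 9 adjusted over the list alone (camera adjusted p = 1.07e-07, and adjusted p = 0.0742 with an estimated correlation). Tnfsf13b was at -0.24 (adjusted p = 0.762) and Mmp2 at 1.36 (0.147), neither past the threshold.

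With RA and Pam2CSK4 together (2 arrays against 2), 873 genes changed from the unstimulated state, 499 higher and 374 lower, and with the deposited median scaling the split was 372 higher and 403 lower. The count was 445 without unstimulated replicate 2, 313 and 375 without replicate 1 or 2 of the combined stimulus, and 1568 without the 4-decimal arrays. Cxcl13 rose by 6.89 ± 0.43, Il6 by 5.68 ± 0.42, the collagen-crosslinking enzyme Lox by 5.26 ± 0.34, Mmp9 by 3.04 ± 0.36, Mmp2 by 2.62 ± 0.42, Ltbp3 by 1.88 ± 0.36 and Tnfsf13b by 1.38 ± 0.25. For Tnfsf13b the adjusted p was 0.0029 (range 0.00136 to 0.0647), and 0.0624 without replicate 1 of the combined stimulus and 0.0647, at 0.78, with the mean of its probe sets, and for Ltbp3 it was 0.00422 (range 0.000213 to 0.0793), and 0.0793 without unstimulated replicate 2. NF-kB and inflammatory genes had 15 of 23 higher and 17 adjusted over the list alone (median 2.25; camera adjusted p = 6.23e-23), and interferon-stimulated genes 8 of 18 and 13 adjusted over the list alone (camera adjusted p = 1.88e-12). Complement genes had 6 of 15 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 5.71e-08). Retinoid genes had 5 of 18 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.000503), with Cyp26b1 at 2.96 ± 0.41 and Aldh1a2 at 2.12 ± 0.31. In the TGF-beta list 3 of 18 were higher and 1 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.0687). Macrophage markers had 3 of 11 higher (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0197, and adjusted p = 0.378 with an estimated correlation). The nuclear receptor gene Pparg fell by 2.50 ± 0.31.

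Tests of the combination against either stimulus alone were added after the data were seen. Whether replicate numbers pair these arrays stays open, and counts with the number as a block are given with the sensitivity results. Against RA alone 208 genes differed, 157 higher and 51 lower, including Cxcl13 (4.22 ± 0.43), Lox (4.07 ± 0.34), the interleukin 12 subunit gene Il12a (3.89 ± 0.37) and Tnfsf13b (1.63 ± 0.25), and Mrc1 fell by 2.38 ± 0.39. Against Pam2CSK4 alone 53 differed, 42 higher and 11 lower, including Adgre4 (4.20 ± 0.44), Lox (2.76 ± 0.34) and Rarb (2.67 ± 0.47), while Ltbp3 (1.61; adjusted p = 0.0771), Tnfsf13b (0.72; 0.584) and Cxcl13 (0.55) did not pass. Against RA the count was 60 or 70 without RA replicate 1 or 2 and 59 or 61 without replicate 1 or 2 of the combination, and Tnfsf13b (adjusted p = 0.0027, range 0.000167 to 0.0743) was at 0.0743 and Mrc1 (range 4.44e-05 to 0.08) at 0.08 without replicate 1 of the combination. Mrc1 was also at 0.061 without RA replicate 1. Against Pam2CSK4 it was 7 or 13 without Pam2CSK4 replicate 1 or 2 and 10 or 11 without replicate 1 or 2 of the combination, and Rarb (adjusted p = 0.0169, range 0.00214 to 0.346) was at 0.327 without Pam2CSK4 replicate 1 and 0.346 without replicate 2 of the combination. The interaction, which asks whether the combination departs from the sum of both log2 effects, gave 0 genes with limma and 746 at an unadjusted p under 0.05, and 39 genes without unstimulated replicate 1. Lists were shifted in it, with cell cycle genes above the sum (median 0.81, 6 higher adjusted over the list alone; camera adjusted p = 2.13e-10, and adjusted p = 0.0538 with an estimated correlation) and macrophage markers under it (median -0.94, 5 lower adjusted over the list alone; camera adjusted p = 1.5e-08, and adjusted p = 0.0538 with an estimated correlation).

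LPS was measured on 1 array at 5 h and 1 at 72 h, each against the 2 unstimulated arrays. At 5 h 19 of 23 NF-kB and inflammatory genes were higher and 21 adjusted over the list alone (median 4.32; camera adjusted p = 1.63e-26), with Il6 at 8.27 ± 0.52 and Cxcl1 at 5.54 ± 0.40. Interferon-stimulated genes had 17 of 18 higher and 18 adjusted over the list alone (median 3.44; camera adjusted p = 1.63e-26), with Cxcl10 at 6.77 ± 0.40 and Ifit3 at 5.44 ± 0.29. Among B-cell attractants and survival factors 4 of 9 were higher, also adjusted over the list alone (camera adjusted p = 0.000736), with Il15 at 3.37 ± 0.32, and Vcam1 rose by 2.79 ± 0.43. Macrophage markers had 4 of 11 higher (camera adjusted p = 0.0309, and adjusted p = 0.328 with an estimated correlation). Pparg fell by 3.31 ± 0.37. In all 2223 genes changed, 913 higher and 1310 lower, with 1228 without unstimulated replicate 1.

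At 72 h NF-kB and inflammatory genes had 15 of 23 higher and 18 adjusted over the list alone (median 3.33; camera adjusted p = 3.97e-22), and interferon-stimulated genes 15 of 18 and 18 adjusted over the list alone (median 1.93; camera adjusted p = 2.34e-18). Matrix genes had 13 of 19 higher and 14 adjusted over the list alone (camera adjusted p = 3.4e-11), with Timp1 at 3.94. Markers of other cells were higher too, with 3 of 11 for macrophages (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00688, and adjusted p = 0.199 with an estimated correlation). Fibroblastic reticular and pericyte markers had 2 of 6 higher each and 3 adjusted over the list alone (camera adjusted p = 0.00688 for both, and adjusted p = 0.166 and adjusted p = 0.262 with an estimated correlation). Neutrophil markers had 2 of 7 higher and 4 adjusted over the list alone (camera adjusted p = 0.00774, and adjusted p = 0.244 with an estimated correlation), and blood endothelial markers 2 of 8, also adjusted over the list alone (camera adjusted p = 0.0332, and adjusted p = 0.166 with an estimated correlation). Lcn2 rose by 7.08 ± 0.86, Cxcl13 by 2.98 ± 0.53, Mmp9 by 2.93 ± 0.44 and Tnfsf13b by 1.09 ± 0.31. The count was 959 genes, 591 higher and 368 lower, with 566 and 630 without unstimulated replicate 1 or 2. A test of the 72 h array against the 5 h array, added after the data were seen, had no replicate on either side and took its spread from the other groups, so it compares these 2 arrays and not the times. It gave 146 genes, 73 in each direction, with the neutrophil gene Stfa3 at 5.09 and Cxcl10 (-4.52), Mx1 (-3.97) and the costimulatory receptor gene Cd40 (-3.86) lower on the 72 h array. Both LPS arrays were written with 4 decimals and the unstimulated arrays with 3, a feature shared by 1 naive and 1 Peyer's patch array. With a term for it, 1653 genes passed at 5 h, 1196 of them from the 2223, and 573 at 72 h, 424 of them from the 959, and the median absolute change of the called genes went from 1.51 to 1.27 and from 1.73 to 1.44. At 72 h the fibroblastic reticular, pericyte and neutrophil lists then did not pass (0.0565, 0.201 and 0.244). Tnfsf13b at 72 h then had an adjusted p of 0.122, against 0.044 without the term (range 0.0347 to 0.204), and 0.101 or 0.123 without unstimulated replicate 1 or 2.

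**Figure D2:**
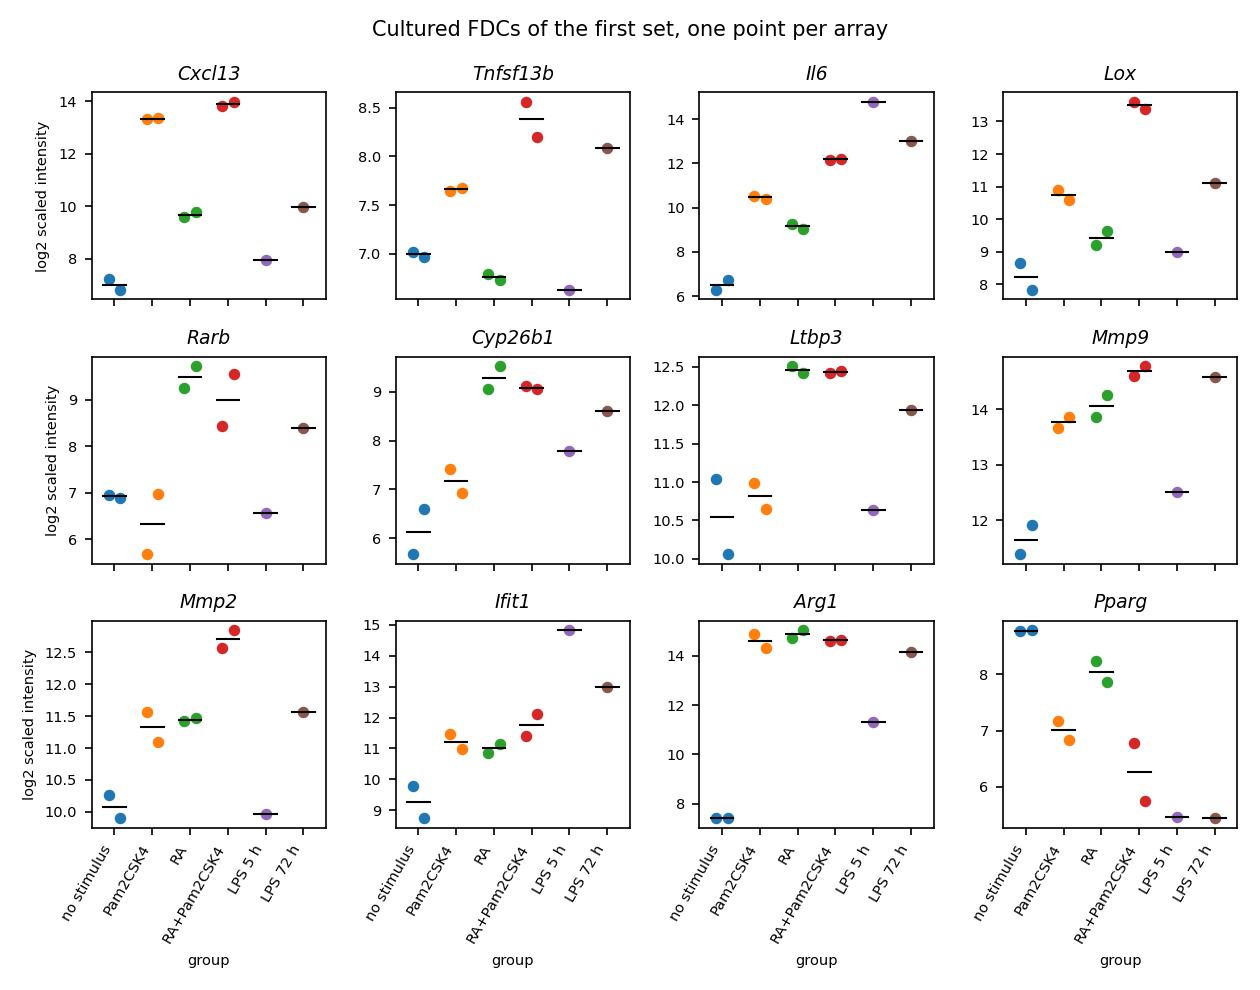
Expression of genes in cultured FDC preparations, as log2 scaled intensity on the vertical axis, by stimulus. Each point is an array and each line a group mean. Against no stimulus, Cxcl13 was higher by 6.34 with Pam2CSK4, 2.67 with RA and 6.89 with both, and Tnfsf13b by 1.38 with both.

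The genes that separate Peyer's patches from naive pLN were then followed in culture, to ask whether RA or Toll-like receptor ligands move them. These lists, 544 genes higher and 512 lower in Peyer's patches, were chosen by differences between freshly prepared arrays. With RA, the Peyer's patch-high genes had a median of 0.24, against -0.066 to 0.019 for matched random lists, and 69.3% of them were above 0, against 48.1% of all genes (camera p = 6.6e-08, adjusted over 12 tests, and adjusted p = 0.125 with an estimated correlation). Of them 32 rose and 3 fell. With Pam2CSK4 the median was 0.13 and 60.1% were above 0 (0.00185, and adjusted p = 0.251 with an estimated correlation), and with both stimuli it was 0.17 and 60.5% (0.000148, and adjusted p = 0.208 with an estimated correlation). At 72 h of LPS the median was also 0.24 and 61.6% were above 0 (0.001, and adjusted p = 0.24 with an estimated correlation), and at 5 h it was -0.008 without passing (0.699). The Peyer's patch-low genes were higher, not lower, with Pam2CSK4 (median 0.16; 0.000982, and adjusted p = 0.143 with an estimated correlation), with both stimuli (0.16; 0.00185, and adjusted p = 0.156 with an estimated correlation) and with LPS at 72 h (0.29; 6.36e-05, and adjusted p = 0.117 with an estimated correlation). With RA their median was -0.028, 18 were called higher and 6 lower, and their test pointed up without passing (0.32). In the second set the Peyer's patch-low genes had a median of -1.05 in unstimulated culture against naive pLN (1 array each). That median lay below all random lists, and 266 of the 512 genes were at least 2-fold lower, against 41 higher. Whether their rise with a stimulus was a return of transcripts lost in culture was not tested. At 5 h of LPS the Peyer's patch-low genes rose, with 186 higher and 27 lower and a median of 0.70 (7.91e-19, and adjusted p = 0.0024 with an estimated correlation). Both LPS comparisons rest on 1 array each, written with 4 decimals, and these lists were not tested with the term for decimals. With the lists cut to genes that differed at least 2-fold, the Peyer's patch-high medians were 0.326 with RA, 0.227 with Pam2CSK4 and 0.357 with both. They were 0.197 at 5 h and 0.44 at 72 h of LPS, so the 5 h median turned above 0. The Peyer's patch-low medians were then 0.013, 0.242, 0.253, 0.866 and 0.406 in the same order. Across genes, the change from naive pLN to Peyer's patches correlated with the change under RA at r = 0.117, under Pam2CSK4 at 0.022, under both at 0.039, under LPS at 5 h at -0.148 and under LPS at 72 h at 0.014, where genes are not independent replicates. With genes permuted, r ran from -0.017 to 0.018 for LPS at 72 h. In the RA by Pam2CSK4 interaction the Peyer's patch-high genes lay under the sum of both effects, with a median of -0.182 and r of -0.085. Camera gave an adjusted p = 0.000619 there, and adjusted p = 0.237 with an estimated correlation.

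Pam3CSK4, a lipopeptide with 1 acyl chain more than Pam2CSK4, was measured on 1 array of the second set, and its change from the unstimulated array of that set was compared with the Pam2CSK4 change of the first set. The dose of Pam3CSK4 was not in the labels. The Pam3CSK4 change is 1 array against 1, with all of its spread taken from the first set, so the test compares these arrays and has no replicate check. Naive and unstimulated arrays of the 2 sets correlated with r of at most 0.88 and 0.87, below the replicates of the first set. With limma 5 genes differed, all with the higher change under Pam3CSK4, and 482 at an unadjusted p under 0.05. These 5, named because they are so few and after their values were seen, were Cd209f (4.86 ± 0.70), Ly6i (4.86 ± 0.72), Gsta2 (3.81 ± 0.62), Vcan (3.65 ± 0.56) and Adam23 (3.53 ± 0.52). With RA present 3 differed, Gsta2 (3.97 ± 0.62), Vcan (3.86 ± 0.56) and Cd1d2 (2.89 ± 0.41), and 553 at an unadjusted p under 0.05. With the deposited median scaling that split was 6 higher and 1 lower, against 3 and 0. The genes had different starting levels, with Vcan at 6.52 in the unstimulated array of the second set and 9.80 in the first, and Gsta2 at 5.21 and 8.89. The first count was 0 without unstimulated replicate 2 or either Pam2CSK4 array and 17 without unstimulated replicate 1. The second was 0 without unstimulated replicate 2 or replicate 2 of RA plus Pam2CSK4, 1 without replicate 1 of that group and 18 without unstimulated replicate 1. For Cxcl13 the difference was -1.29 (95% interval -2.88 to 0.30), for Mmp2 2.05 (0.50 to 3.61), for Tlr2 1.64 (0.47 to 2.81) and for Tnfsf13b 0.56 (-0.35 to 1.48), each with an adjusted p of 0.999.

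The freshly prepared cells of the second set were pLN preparations from naive mice and from mice given complete Freund's adjuvant (CFA) with or without a compound labelled only Pam, with 1 array each, so differences have no replicate check. After CFA, 619 genes were at least 2-fold higher and 156 lower. The immunoglobulin gene Ighg3 was 5.98 log2 units higher, C1qa 4.48 and Mmp9 2.11, and Cxcl13 was at -0.28. Interferon-stimulated genes had a median of -0.91, below all matched random lists, and B-cell markers one of 0.57, at percentile 99.1. The genes high in Peyer's patches had a median of 0.20, at the 100th percentile, and the genes low there one of -0.43, below all random lists. After CFA with Pam these 2 medians were 0.32 and -0.43 against naive, at the same percentiles. Of 6971 genes chosen in the same way, 34 were at least 2-fold higher with CFA and Pam than with CFA, and 15 lower. Igha was at 3.41, Ctla4 at 2.84 and the plasma-cell gene Mzb1 at 2.01. The cell cycle list (median 0.65) and the plasma-cell list (0.72) stood at the 100th percentile of random lists, as did the matrix list (0.52). Pericyte (0.59), dendritic-cell (0.51) and FDC-associated (0.21) genes stood at percentiles 99.9, 99.8 and 99.8, and retinoid (0.24), blood endothelial (0.37) and T-cell (0.34) genes at 98.4, 98.5 and 97.6.

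Cultured cells of the second set had 1 array per stimulus, each set against the same unstimulated array of that set, with no replicate check. A deviation of that array, or its unstated culture time, could appear with every stimulus and cannot be told apart from it. Arg1 was higher by 7.56 log2 units with RA and LPS and 6.49 with RA, Pam2CSK4 and LPS. It was higher by 6.41 with Pam3CSK4, 7.50 with RA and Pam3CSK4 and 7.44 with RA, Pam2CSK4 and Pam3CSK4. Cxcl13 was higher by 4.08, 2.80, 5.05, 5.44 and 5.34 in the same order, and Tnfsf13b by 3.86, 3.63, 1.23, 2.66 and 3.27. Mmp2 was at 3.59 with RA and LPS, 1.33 with RA, Pam2CSK4 and LPS, 3.30 with Pam3CSK4, 4.48 with RA and Pam3CSK4 and 4.79 with RA and both lipopeptides. Ltbp3, which rose with RA in the first set, was at 0.31, -0.13, -0.17, 0.40 and 0.55, Mmp9 at 1.35, 1.04, 0.97, 1.53 and 1.57 and Rarb at 1.84, 1.14, -0.06, 1.88 and 1.79. NF-kB and inflammatory genes had medians of 2.71, 2.80, 2.32, 2.85 and 2.96. Neutrophil markers were higher in the same arrays, with medians of 1.75, 0.67, 1.05, 1.30 and 1.75 at percentiles 99.5 to 100 of random lists. Macrophage markers had medians of -0.29, -0.43, 0.20, 0.31 and 0.19, at percentiles 1.29, 0.66, 97.2, 99.1 and 90.6. In the 3 arrays with Pam3CSK4, plasma-cell markers had medians of 0.69, 0.79 and 0.79, at percentiles 99.9 to 100. Their median was 0.42 with RA and LPS (percentile 99.3) and 0.19 with RA, Pam2CSK4 and LPS (86.6). The Pam3CSK4 arrays had blood endothelial medians of -0.32, -0.53 and -0.59, at percentiles 0.2 to 1.29. Lymphatic endothelial medians there were -0.41, -0.69 and -0.88, at percentiles 0.1 to 1.41. The genes high in Peyer's patches had medians of -0.05 with RA and LPS, -0.18 with RA, Pam2CSK4 and LPS, 0.05 with Pam3CSK4, 0.18 with RA and Pam3CSK4 and 0.21 with RA and both lipopeptides. For Pam3CSK4 that median was -0.02 under quantile normalization. The genes low in Peyer's patches had medians of 0.25, 0.27, 0.31, 0.25 and 0.28 in the same order, each at the 100th percentile of random lists.

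**Figure D3:**
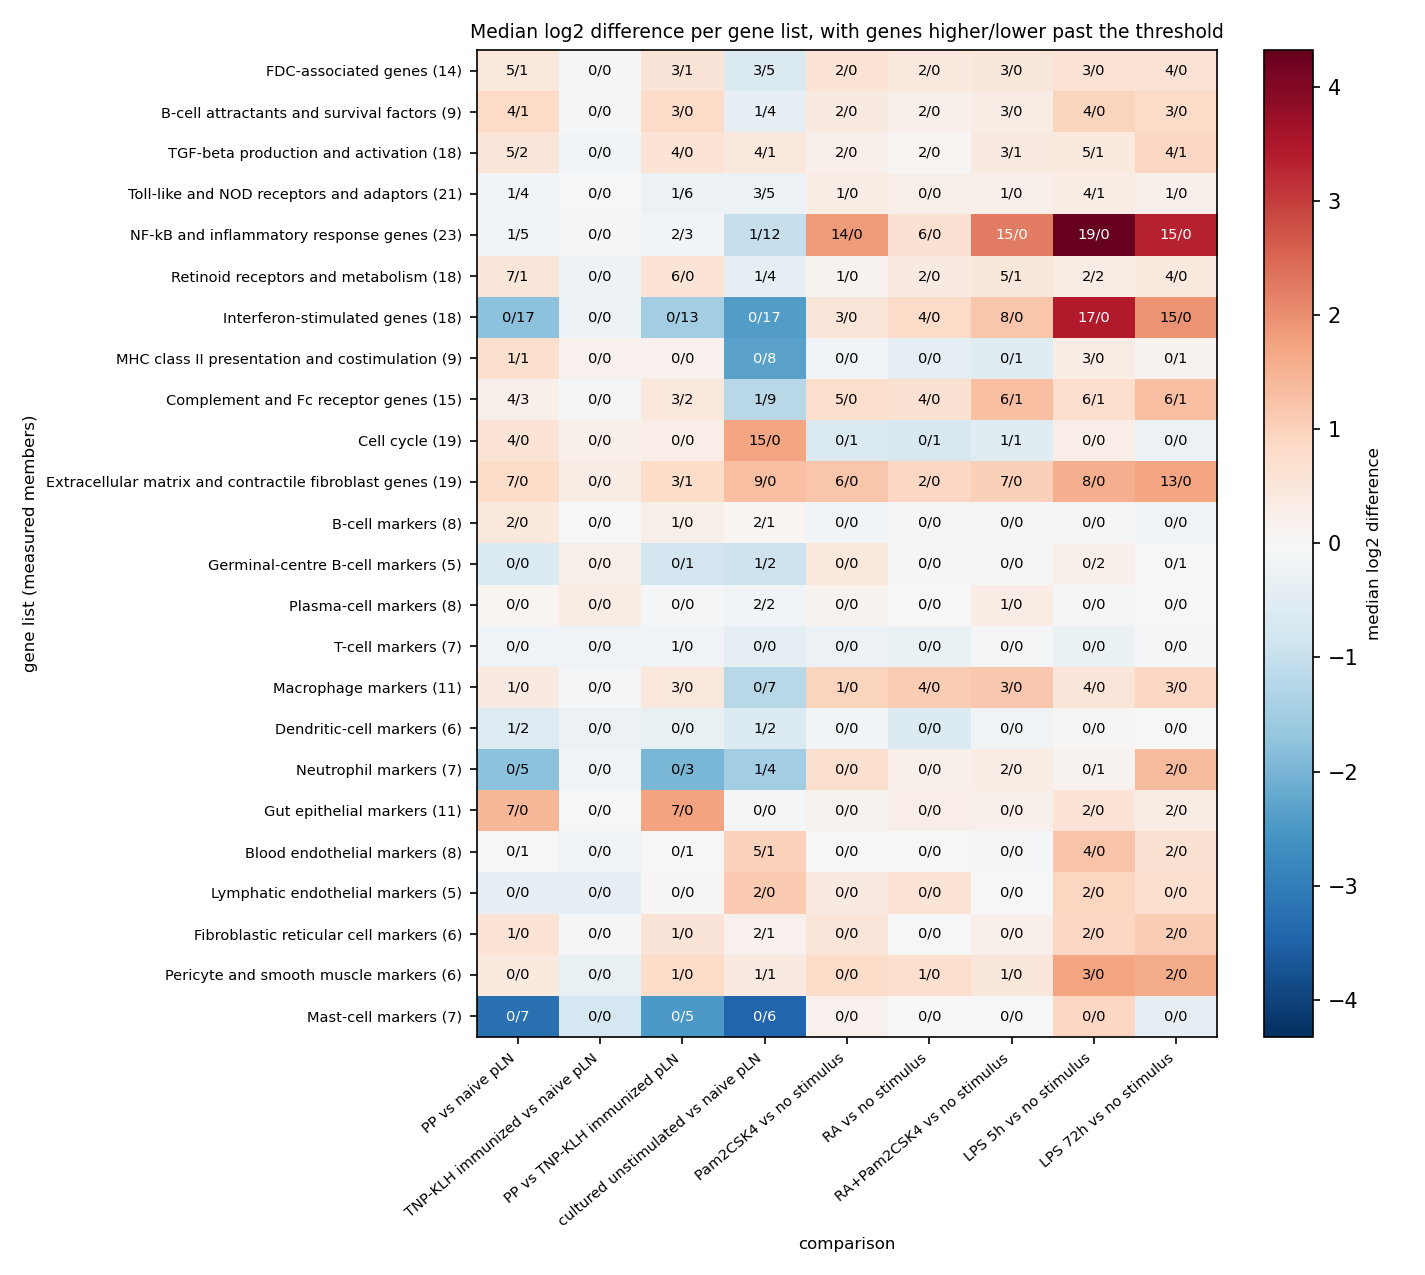
Median log2 difference of the members of each fixed gene list (vertical axis, measured members in brackets) for the comparisons of the first set (horizontal axis), as colour, with the numbers of members higher and lower past the threshold in each field. Interferon-stimulated genes are low in Peyer's patches (-1.77) and in unstimulated culture (-2.40) and high after LPS for 5 h (3.44), and NF-kB and inflammatory genes are high with Pam2CSK4 (1.85).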

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

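Of the tests here, the comparison of LPS at 72 h with 5 h, the test of fewer macrophages as the whole cause and the test of the epithelial list between arrays written with 3 decimals were chosen after the results were seen. A test of the difference between the changes found 5 genes for Pam3CSK4 against Pam2CSK4 and 3 genes with RA added, and the test of the LPS array at 72 h against that at 5 h found 146 genes. These tests rest on single arrays with the spread borrowed from other groups, so they compare the arrays and not the conditions.

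Markers of macrophages were lower in unstimulated culture than in naive pLN preparations, with a median of -1.21 (adjusted p = 0.0501 with an estimated correlation), and in the second set the median of -0.59 lay inside the range of random lists. Fewer macrophages as the whole cause is argued against by a second list of 22 genes shared by macrophages, of which 18 lay above -1.21 by more than 2 standard errors, such as Tyrobp (0.04), Ctss (-0.03) and Itgam (2.05). Separate processing of some arrays is argued against too, since the median was -1.37 against the naive arrays written with 3 decimals like the cultures. A partial loss of macrophages stays open, because the second list had a median of -0.33 with 4 members higher and 5 lower. The SE of that median, 0.19, came from resampling the 22 genes as if independent. It does not measure the spread between arrays. A change of expression in culture, which the design names, stays open and was not tested.

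Gut epithelial genes were higher in Peyer's patch preparations than in those of naive pLN, with a median of 1.42 (adjusted p = 0.11 with an estimated correlation). Among the arrays written with 3 decimals the median was also 1.42. This says little on separate processing, since naive replicate 1 and Peyer's patch replicate 1 were both written with 4 decimals. A shift common to these arrays cancels between the groups, with or without them. Epithelial cells in the preparations may contribute, and this stays open. Of 30 genes of a second epithelial list 7 were called higher and 0 lower, against 2.63% of all 18193 genes called higher, with Fabp6 at 3.24 ± 0.49. The exact 95% interval of that share, 9.93% to 42.3%, treats the genes as independent, though they were measured on the same arrays. That share lay just under the bound set beforehand but within its interval of it, and the rule that such a value decides nothing was applied after the value was seen. The second list had a median of 0.93, and 15 of its 30 members were at least 2-fold higher without regard to the test. Whether epithelial cells contribute to other genes higher in Peyer's patches was not tested. The difference between the tissues themselves, which the design names, also stays open and was not tested.

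Genes high in Peyer's patches had a median of 0.24 with RA in culture, with 32 of 544 called higher and 3 lower and an adjusted p = 0.125 with an estimated correlation. That median stood at the 100th percentile of 10000 random lists matched on the difference between culture and naive pLN. These ran from -0.089 to 0.003, but take no account of correlation between genes, so the range may be too narrow. A return of transcripts lost in culture thus stays open. The median was 0.323 without unstimulated replicate 1 and 0.133 without replicate 2. Each stood at the 100th percentile of lists matched on expression, which share that limit. Neither array alone carried the sign of the shift, but its size moved with them. With LPS at 72 h and Pam2CSK4 the median was 0.236 and 0.131, but there the Peyer's patch-low genes were higher as well (0.286 and 0.164). With RA the Peyer's patch-low median was -0.028, and 0.013 for those with at least a 2-fold difference. Of the Peyer's patch-low genes 18 were called higher with RA and 6 lower. A return of transcripts lost in culture was not tested for the Peyer's patch-low genes. A part of RA in the Peyer's patch pattern stays open, since that list test did not pass and the low genes did not fall with RA.

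Chance in the grouping of the 3 Peyer's patch and 3 naive arrays was examined by counting splits. The real split gave 1056 genes and was the 1 split of 10 with as many. The highest of the others gave 118, with naive replicate 1 and Peyer's patch replicates 1 and 3 together, and 10 splits are too few for a share under 0.05. The 3 other splits that part all the pairs gave 0 genes each, and differ from the real one in exchanging the tissues of 1 pair.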

How the results depend on the processing

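The deposited median scaling, the term for decimals and the removal of the 4-decimal arrays were chosen after the data were seen, as were the comparisons of RA plus Pam2CSK4 with either stimulus and of LPS at 72 h with 5 h. Of 14078 values of named genes under the alternatives, 12997 kept their side of the threshold, 755 lost the call and 326 gained one. None of the values past the threshold changed sign. Of 637 list tests 483, 140 and 14 did so, with 0 changes of sign. A change of sign was counted only for values past the threshold in the main test, so others may have turned. Of 918 untested values of the second set 743 counted as unchanged, 174 as moved and 1 as changed in sign. A single gene counted as moved when it shifted by at least the median limma SD of the first set. A list median counted as moved when it entered or left the range of random lists. Sign was followed only for list medians outside that range. The 1 that changed was the median of Peyer's patch-high genes with Pam3CSK4, which was 0.05 and became -0.02 under quantile normalization. Counts of genes moved by over 1.5 times as follows, and the cause was not tested except where fewer arrays were used. Quantile normalization gave 8 genes for RA plus Pam3CSK4 against RA plus Pam2CSK4. An added value of 8 gave 3 for Pam3CSK4 against Pam2CSK4, and the larger added value gave 8 for the interaction and 11 for RA plus Pam3CSK4. The 75th percentile filter gave 3 for Pam3CSK4, the mean of probe sets 1 for RA plus Pam3CSK4, and no intensity trend 2 for Pam3CSK4 and 0 for RA plus Pam3CSK4. The deposited median scaling gave 2 for the interaction, 96 for LPS at 72 h against 5 h, 11 for Pam3CSK4 and 7 for RA plus Pam3CSK4.

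Array weights gave 11 genes for TNP-KLH, 1529 for Peyer's patches against TNP-KLH, 435 for Pam2CSK4, 483 for RA, 1678 for both, 21 for the interaction, 1732 for LPS at 72 h, 604 for both stimuli against RA, 149 against Pam2CSK4, 439 for LPS at 72 h against 5 h, 10 for Pam3CSK4 and 14 for RA plus Pam3CSK4. The term for decimals gave 1602 for Peyer's patches against naive pLN, 8 for TNP-KLH, 711 for Pam2CSK4, 552 for RA, 1688 for both, 13 for the interaction, 573 for LPS at 72 h, 334 for both against RA, 80 against Pam2CSK4 and 405 for LPS at 72 h against 5 h. Without the 4-decimal arrays the counts were 4 for TNP-KLH, 575 for Pam2CSK4, 488 for RA, 1568 for both and 2 for the interaction. With the spread of the compared groups only they were 479 for Peyer's patches against naive pLN, 0 for TNP-KLH, 509 for Peyer's patches against TNP-KLH, 2233 for unstimulated culture, 383 for RA, 2 for the interaction and 445 for both against RA. Adding the second set's naive and unstimulated arrays gave 1 for TNP-KLH, 1 for the interaction, 135 for both against RA and 89 for LPS at 72 h against 5 h.

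Leaving out single arrays gave 734 to 1071 genes for Peyer's patches against naive pLN, 0 to 31 for TNP-KLH, 291 to 1099 for Peyer's patches against TNP-KLH, 2185 to 3539 for unstimulated culture, 67 to 266 for Pam2CSK4, 40 to 276 for RA, 313 to 630 for both and 0 to 39 for the interaction. For LPS the ranges were 1228 to 1700 at 5 h and 566 to 630 at 72 h, for Pam3CSK4 0 to 17, for RA plus Pam3CSK4 0 to 18, and for both stimuli 59 to 70 against RA and 7 to 13 against Pam2CSK4. A lone array left in a group was assumed to vary like the other groups. Of the list tests, 81 outside LPS and 26 with LPS passed, and 20 and 8 with an estimated correlation. Of 12 tests of the Peyer's patch lists in culture 9 passed, and 1 with an estimated correlation.

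The replicate block gave 1653 genes for Peyer's patches against naive pLN, where the numbers pair the arrays, and 1051 of the 1056 genes were among them. Among the genes named by the rule and the lists, it changed no call there other than those given with that comparison. Correlations of same-numbered deviations were 0.296 to 0.398 among Pam2CSK4, RA and both, above the 0.1 taken as pairing. With 2 arrays in a group the deviations mirror each other. Each of these correlations is thus a single value, and pairing there stays open. They were -0.0718 to 0.0522 with the unstimulated arrays and -0.0971 to -0.0205 with TNP-KLH. In these other comparisons the block gave 687 for TNP-KLH, 2602 for Peyer's patches against TNP-KLH, 4495 for unstimulated culture, 817 for Pam2CSK4, 600 for RA, 1688 for both, 19 for the interaction, 342 for both against RA and 96 against Pam2CSK4. The signal over background of the arrays was not given in the sources used here.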

Other observations

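The test with a term for decimals was chosen after the results were seen. In unstimulated culture the genes with the largest rise from naive pLN preparations included the transporter gene Slco4a1 (6.36 ± 0.32; SE, 2 arrays against 3), the ubiquitin ligase gene Rnf128 (6.09 ± 0.33), the macrophage elastase gene Mmp12 (5.89 ± 0.27) and Atp6v0d2, a proton pump subunit of osteoclasts (5.83). Those with the largest fall included the lectin gene Cd209b (-7.65 ± 0.37), the chemokine gene Cxcl9 (-7.60 ± 0.39), Timd4 (-6.68) and Hdc, which makes histamine (-6.52). Blood endothelial markers went both ways, 5 of 8 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.0918), with Vwf at 3.50 ± 0.40, Cdh5 at 1.26 ± 0.23 and Kdr at -2.59 ± 0.25. In the second set, with 1 array each, the median of this list was 2.46, at the 100th percentile of random lists. There 6 members were at least 2-fold higher and 1 lower.

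Some endothelial, pericyte and reticular cell markers were higher after 5 h of LPS than without a stimulus, though none of these lists passed with an estimated correlation. Blood endothelial markers had 4 of 8 higher and 6 adjusted over the list alone (camera adjusted p = 0.00263, and adjusted p = 0.0682 with an estimated correlation), with Emcn at 2.34 ± 0.52 and Cdh5 at 1.42 ± 0.31. Pericyte and smooth muscle markers had 3 of 6 higher and 4 adjusted over the list alone (camera adjusted p = 0.00927, and adjusted p = 0.328 with an estimated correlation), and with a term for the decimals of the values the list test gave 0.166. Fibroblastic reticular markers had 2 of 6 higher and 3 adjusted over the list alone (camera adjusted p = 0.0309, adjusted p = 0.328 with an estimated correlation, and 0.225 with the term), and lymphatic endothelial markers 2 of 5, also adjusted over the list alone (camera adjusted p = 0.0233, adjusted p = 0.0872 with an estimated correlation, and 0.0537 with the term). The blood endothelial list passed with the term (0.00185). These values rest on 1 LPS array.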
